A study of Mus musculus with 12 samples.

How the data were processed

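RNA of laser-captured conjunctival forniceal epithelium was amplified by the authors in 2 cycles and hybridized to 12 Affymetrix arrays of 45101 probe sets. There were 3 samples each of wild type at PN9, PN14 and PN20 and of Klf4CN at PN14. The deposited signal intensities were made by the authors with GCOS 1.4, on a linear scale, each array scaled so that its 2% trimmed mean is 150. Tested on the tables, the trimmed means lay between 149.35 and 149.96. The deposited score of each probe set for each of the 4 pairs of groups was made by the authors as the sum of increases and decreases over 9 pairwise comparisons of arrays. The other deposited columns were made by the authors as the number of Present calls among the 3 arrays of each group and a code for the comparisons passed. By their rule a comparison passes when all 3 arrays of the higher group are Present, the groups do not overlap, the means differ over 2-fold and the sum lies beyond 5. The series table and the other deposited table hold identical intensities (largest difference 0), so using that other table in place of the first cannot change a value. All 24 per-sample columns were mapped to a sample.

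A probe set was kept when it lay above the 40th percentile of its own array on at least 3 arrays, and 30600 were kept. The medians of kept probe sets ranged from 70.9 to 91.85, a difference of 29.5%. A difference above 10% called for scaling to a common median by a rule set before the data were examined, which did not say over which probe sets. The median of the kept probe sets was used, with factors of 0.8761 to 1.135, and values as deposited and the median of all probe sets were alternatives. Values were taken as log2(signal + 16). Of the probe sets 34958 had 1 gene symbol in the platform annotation, matched to current symbols through a RefSeq gene table, 932 had several and 9211 none (64 of these are controls), and the latter 2 kinds were left out of gene counts. Each gene was represented by its kept probe set of highest mean, leaving 14163 genes, of which 6402 had over 1 kept probe set. Of the kept probe sets 2298 were Present on no array. The signal, not a read depth, sets the precision: dim genes have folds pulled toward 1 by the offset.

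Groups were compared with limma 3.58.1 in R 4.3.3, fitting 1 mean per group to all 12 arrays with a trended moderated variance (8 residual and 6.87 prior degrees of freedom) and Benjamini-Hochberg adjustment over the genes. A gene passed at an adjusted p under 0.05, and errors of log2 changes are limma's standard errors. Change over the 3 ages was tested with limma's moderated F. The choices of comparisons, tests, thresholds, filter, gene lists and alternative settings, apart from the 5 settings named below, were made before the data were examined. Lists of genes were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over 140 tests (35 lists in 4 comparisons). With that small correlation 67 tests passed. With an estimated correlation 0 passed (lowest adjusted p 0.147, and 13 at an unadjusted p under 0.05), and by limma's fry 34 did. Overlaps of called genes were tested with Fisher's exact test, and the score per array with an exact permutation test, whose p cannot go below 0.1 for 3 arrays against 3. A fold against a group with no Present call of the gene's best probe set is a bound. For the bound each array of that group was set to at least its lowest value among probe sets Present on all 3 arrays of the group, and no fold is given when both groups lack Present calls.

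The lists, with 908 genes in all, cover goblet cells and gel-forming mucins, membrane mucins, mucosal keratins, basal epithelium, cornification, wound keratins, corneal epithelium, cell junctions, cell cycle, inflammatory genes, innate defence, interferon response, class II antigen presentation, retinoid, glutathione, Notch, Wnt, TGF-beta and BMP, epithelial transcription factors, ion and water transport, secretory endoplasmic reticulum, lipid synthesis, ribosomal proteins, respiratory chain, circadian clock and sex-linked genes. Another 9 lists hold markers of fibroblasts, endothelium, skeletal muscle, lymphocytes, myeloid cells, melanocytes and Schwann cells, lens and retina, glands and hair follicle. Genes to name in each comparison were fixed by rule. They are Klf4, the 8 genes of largest change in each direction among those that passed with non-overlapping groups (clone names left out), up to 4 members of each list by size of change (or the 2 of smallest p where none passed), and up to 5 genes each that passed from PN9 to PN20 and in Klf4CN in opposite or equal directions. Not every gene that the rule yields is printed.

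Alternatives covered the offset, the scaling, the filter, the choice of probe set, the variance model, array weights, the ordinary test, the threshold, a minimum fold, a replicate block, the samples fitted and leaving out each array. Chosen after the data were seen were values as deposited, the median of all probe sets, sex (Xist) and the actin 3' to 5' ratio as covariates, and leaving out the 2 arrays of highest added control RNA. In simulated data of the same size and spread the 4 comparisons recovered 50%, 47%, 47% and 56% of 100 genes changed 2-fold. They recovered 97%, 91%, 95% and 94% of 100 changed 4-fold. Of 158, 142, 146 and 154 calls 11, 4, 4 and 4 were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.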

Results

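RNA from the epithelial layer of the mouse conjunctival fornix, the recess where the lining of the eyelid turns onto the eyeball, was collected by laser capture. It was measured on 12 Affymetrix arrays of 45101 probe sets, with 1 array per sample. The 12 samples fell into 4 groups of 3: wild type at postnatal day 9 (PN9), day 14 (PN14) and day 20 (PN20), and animals labelled Klf4CN at PN14. The labels describe Klf4CN as a conditional knockout of Klf4, a gene for a zinc finger transcription factor. The comparisons of age ask how expression in this epithelium changes after birth, and the comparison of genotype asks which of its genes depend on Klf4. The labels call the samples independent but tie none of them to an animal, so the p-values measure only the spread between these samples, which may be technical. The filter kept 14163 genes, and the number of arrays, 3 per group, limits the precision of every value. Levels are array signals (mean ± SD, n = 3), and each fold is on the log2(signal + 16) scale, which understates the change of genes of low signal. A fold is followed in parentheses by the log2 change ± its standard error and by limma's adjusted p. "At least" marks a fold against a group in which no array had a Present call. Unless said otherwise, the 3 arrays of one group lay wholly above or below the 3 of the other for each named gene that passed.

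Array quality moved with age. The ratio of the 3' to the 5' beta-actin control, a sign of RNA quality that is higher in degraded or shortened RNA, was 34.9 ± 11.4 at PN9, 19.0 ± 7.14 at PN14, 12.7 ± 3.45 at PN20 and 12.7 ± 6.44 in Klf4CN (SD, n = 3). Replicate arrays of 1 group correlated with Pearson's r between 0.9211 and 0.9785 over all probe sets, and the 2 lowest values belonged to Klf4CN replicate 3, with 0.9317 and 0.9211. On that array the 18S ribosomal RNA control probe sets stood at 12150, against 6514 on the highest wild-type array. Xist, the transcript of the inactive X chromosome, was high on 7 arrays: all 3 of Klf4CN, PN14 replicates 1 and 2, PN9 replicate 2 and PN20 replicate 1. Replicates of PN9, PN14 and PN20 are wild type throughout.

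Klf4 was measured by 2 probe sets. The brighter one read 3015 ± 338.5 at PN9, 5498 ± 1233 at PN14, 7131 ± 35.41 at PN20 and 9052 ± 1765 in the samples labelled Klf4CN (SD, n = 3). Its signal rose 1.8-fold (log2 change 0.85 ± 0.20, adjusted p = 0.0205) from PN9 to PN14 and 2.37-fold (log2 change 1.24 ± 0.20, adjusted p = 0.00057) from PN9 to PN20. From PN14 to PN20 it was 1.32-fold (log2 change 0.40 ± 0.20, adjusted p = 0.331) higher, which did not pass. The 3 arrays labelled Klf4CN read 10920, 8815 and 7417, each above the 3 wild-type arrays of the same age at 4385, 6824 and 5285, but the difference of 1.65-fold (log2 change 0.72 ± 0.20, adjusted p = 0.229) did not pass. The dimmer probe set read 556.7 ± 220.0, 1040 ± 441.2, 493.9 ± 146.5 and 2229 ± 1567 in the same order. It differed from the brighter one in sign from PN14 to PN20, with a log2 change of -1.02 and an unadjusted limma p of 0.0421, and from PN9 to PN20, with -0.13 and an unadjusted limma p of 0.775. The labels do not say which part of the gene was deleted, and whether these probe sets lie within it is not given in the sources used here, so the Klf4 signal does not check the labels. The rise from PN9 to PN14 missed the threshold without PN9 replicate 1 (adjusted p = 0.0887), PN9 replicate 2 (adjusted p = 0.0579) or PN14 replicate 2 (adjusted p = 0.0986).

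Between PN9 and PN14, genes of goblet cells, surface mucins, water transport and mucosal defence rose. Muc5ac, the gel-forming mucin of goblet cells, went from 109.7 ± 96.0 to 821 ± 279.6, or 8.38-fold (log2 change 3.07 ± 0.50, adjusted p = 0.00336) higher. Of 24 measured goblet cell and gel-forming mucin genes, 10 rose, and 12 did when adjusted over the list alone. Goblet cell genes had a median log2 change of 0.85 (camera adjusted p = 5.8e-08, adjusted p = 0.279 with an estimated correlation). Among them were Tspan8, a tetraspanin, at 6.3-fold (2.66 ± 0.41, adjusted p = 0.00268), Agr2, an endoplasmic reticulum protein needed for mucin production, at 4.38-fold (2.13 ± 0.33, adjusted p = 0.00268), and Gcnt3, an enzyme that branches mucin sugars, at 3.75-fold (1.91 ± 0.28, adjusted p = 0.00196). Of 16 membrane mucin and glycocalyx genes 6 rose, 8 adjusted over the list alone. Membrane mucin genes had a median log2 change of 0.65 (camera adjusted p = 0.000289, adjusted p = 0.489 with an estimated correlation). Those called included Muc16 at 3.04-fold (1.61 ± 0.30, adjusted p = 0.0082) and Muc4 at 6.13-fold (2.62 ± 0.63, adjusted p = 0.0254). Of 29 ion and water transport genes 7 rose, 9 adjusted over the list alone. Transport genes had a median log2 change of 0.52 (camera adjusted p = 0.000366, adjusted p = 0.498 with an estimated correlation). The water channels Aqp5, at 13.6-fold (3.77 ± 0.37, adjusted p = 0.00016), and Aqp4, at 10.7-fold (3.42 ± 0.51, adjusted p = 0.00222), were among those called. Slc5a1, a sodium and glucose cotransporter, rose 21.1-fold (4.40 ± 0.39, adjusted p = 8.09e-05), and Gp2, a membrane glycoprotein that binds bacteria, rose 16.6-fold (4.05 ± 0.49, adjusted p = 0.000543). Of 9 simple and mucosal keratins 4 rose, with 4 higher and 1 lower adjusted over the list alone. Mucosal keratins had a median log2 change of 0.34 (camera adjusted p = 0.0362, adjusted p = 0.614 with an estimated correlation), with a median of 0.52 without PN9 replicate 2 and 0.12 without PN9 replicate 3. Krt23 rose at least 5.68-fold (2.51 ± 0.36, adjusted p = 0.00159) and Krt78 3.83-fold (1.94 ± 0.31, adjusted p = 0.00337), while the list's call ended without PN9 replicate 3, PN14 replicate 2 or PN14 replicate 3 (highest adjusted p with 1 array left out, 0.187).

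Defence, lipid and junction genes rose over the same days. Of 39 interferon response genes 9 rose, 14 adjusted over the list alone. Interferon response genes had a median log2 change of 0.56 (camera adjusted p = 1.79e-06, adjusted p = 0.556 with an estimated correlation). Those called included Ifit1 at 6.02-fold (2.59 ± 0.49, adjusted p = 0.0082). Ifit1bl1, a relative of Ifit1 outside the list, went from 322 ± 55.2 to 5452 ± 819.5 and rose 16.2-fold (4.02 ± 0.29, adjusted p = 1.01e-05). Of 30 innate receptor and antimicrobial genes 5 rose, 12 adjusted over the list alone. Innate defence genes had a median log2 change of 0.54 (camera adjusted p = 0.000241, adjusted p = 0.478 with an estimated correlation). Pglyrp1, which binds bacterial peptidoglycan, rose 11-fold (3.46 ± 0.55, adjusted p = 0.00321), and Pigr, which carries immunoglobulin A across epithelia, rose 6.59-fold (2.72 ± 0.49, adjusted p = 0.00722). Of 24 myeloid and mast cell genes 4 rose, 5 adjusted over the list alone. Myeloid and mast cell genes had a median log2 change of 0.12 (camera adjusted p = 0.0275, adjusted p = 0.494 with an estimated correlation), with a median of 0.28 without PN9 replicate 2 and 0.22 without PN14 replicate 3, and the call ended without PN9 replicate 1 or PN14 replicate 1 (highest adjusted p with 1 array left out, 0.0772) and with the actin ratio as a covariate (median 0.20, adjusted p = 0.0797). Of 34 lipid and cholesterol synthesis genes 11 rose, 17 adjusted over the list alone. Lipid synthesis genes had a median log2 change of 0.77 (camera adjusted p = 1.57e-06, adjusted p = 0.509 with an estimated correlation), with a median of 0.44 without PN14 replicate 3. Those called included the sterol enzymes Msmo1 at 9.47-fold (3.24 ± 0.51, adjusted p = 0.00304), Sc5d at 4.63-fold (2.21 ± 0.30, adjusted p = 0.00102) and Cyp51 at 4.47-fold (2.16 ± 0.29, adjusted p = 0.000983). Of 9 markers of sebaceous, meibomian and lacrimal glands 1 rose, 5 adjusted over the list alone. Gland markers had a median log2 change of 1.37 (camera adjusted p = 0.0128, adjusted p = 0.556 with an estimated correlation). This call ended without PN14 replicate 3 (the highest adjusted p with 1 array left out, 0.0568). The mean log2 level of the lipid genes on PN14 replicates 1, 2 and 3 was 9.09, 8.85 and 9.82, and that of the gland markers 7.32, 5.89 and 8.04. Of 33 cell junction genes 6 rose, 8 adjusted over the list alone. Junction genes had a median log2 change of 0.47 (camera adjusted p = 0.000614, adjusted p = 0.614 with an estimated correlation), with a median of 0.31 without PN9 replicate 3 and 0.29 without PN14 replicate 2. Those called included the claudins Cldn23 at 4.76-fold (2.25 ± 0.42, adjusted p = 0.00817) and Cldn7 at 4.21-fold (2.07 ± 0.33, adjusted p = 0.00321). Of 37 endoplasmic reticulum secretory genes 7 rose and 2 fell, 15 and 2 adjusted over the list alone. Secretory genes had a median log2 change of 0.39 (camera adjusted p = 0.000614, adjusted p = 0.53 with an estimated correlation).

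Genes that fell from PN9 to PN14 included Igf2, a fetal growth factor, which went from 5312 ± 2173 to 1241 ± 254 and was 4.09-fold (-2.03 ± 0.27, adjusted p = 0.000983) lower. Cxcl13, a chemokine for B cells, was 4-fold (standard error 0.32 on the log2 scale, adjusted p = 0.00299) lower, and the collagen gene Col12a1 was 4.38-fold (-2.13 ± 0.34, adjusted p = 0.00304) lower. Of 56 cell cycle genes 2 fell, 2 adjusted over the list alone. The list's median log2 change was -0.27 (camera adjusted p = 0.000912, adjusted p = 0.614 with an estimated correlation). Those called were Gins2 at 2.16-fold (-1.11 ± 0.21, adjusted p = 0.008) and Mcm7 at 1.87-fold (-0.90 ± 0.20, adjusted p = 0.0161), both parts of the replication helicase. Markers of other cell types moved too. Of 29 fibroblast and stroma genes 6 fell, 7 adjusted over the list alone. Stromal genes had a median log2 change of -0.44 (camera adjusted p = 8.44e-06, adjusted p = 0.478 with an estimated correlation), with a median of -0.26 without PN9 replicate 2. Those called included Col6a1 at 1.96-fold (-0.97 ± 0.18, adjusted p = 0.00802). Of 24 skeletal muscle genes 6 rose, 20 adjusted over the list alone. Muscle genes had a median log2 change of 2.18 (camera adjusted p = 3.76e-09, adjusted p = 0.509 with an estimated correlation), with a median of 1.4 without PN9 replicate 1. Myh4, a fast muscle myosin, went from 54.3 ± 76.0 to 3278 ± 1199, or 65.4-fold (6.03 ± 0.90, adjusted p = 0.00214) higher, and Pvalb, a calcium buffer of fast muscle, was 15.3-fold (3.94 ± 0.70, adjusted p = 0.00678) higher. Of 27 lens and retina genes 2 rose, 3 adjusted over the list alone. Lens and retina genes had a median log2 change of 0.92 (camera adjusted p = 9e-04, adjusted p = 0.614 with an estimated correlation), with a median of 0.57 without PN9 replicate 2. Those called included Gnat1, the rod transducin, by at least 8.75-fold (3.27 ± 0.62, adjusted p = 0.00837), and that list's call ended without PN9 replicate 2 (the highest adjusted p with 1 array left out, 0.135). The mean actin ratio fell from 34.9 to 19.0.

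In all, limma called 969 of 14163 genes between PN9 and PN14 at an adjusted p under 0.05, with 609 higher and 360 lower. The groups did not overlap for 29.8% of genes, where chance gives 10%. Of the calls, 62.8% were higher, against 48.6% with the values as deposited and 76% with scaling to the median of all probe sets. The count was 275 without PN9 replicate 1, 494 without PN9 replicate 2, 302 without PN14 replicate 1, 388 without PN14 replicate 2, 639 without PN20 replicate 3, 1964 without Klf4CN replicate 3 and 133 with the actin ratio as a covariate. Of the 45 genes of this text that the naming rule gives for this comparison and that passed, 30 passed whichever array was left out, and the calls lost were 13 (without PN9 replicate 1 or PN14 replicate 1), 12 (without PN14 replicate 2), 10 (without PN9 replicate 2), 6 (without PN14 replicate 3), 5 (without PN9 replicate 3 or PN20 replicates 2 or 3), 3 (without PN20 replicate 1) and 2 (without Klf4CN replicate 1).

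Between PN14 and PN20 the goblet cell list and single genes of defence rose, while genes of stroma and of endothelial and mural cells fell. Foxa3, a forkhead factor of secretory epithelia, went from 33.8 ± 12.8 to 179 ± 28.0 and rose 3.98-fold (standard error 0.25 on the log2 scale, adjusted p = 0.00388), and Gcnt3 rose 4.12-fold (2.04 ± 0.28, adjusted p = 0.00511). Tff1, a trefoil peptide secreted with mucins, rose 2.41-fold (1.27 ± 0.21, adjusted p = 0.0112), and Spdef, a transcription factor needed for goblet cell differentiation, rose 2.15-fold (1.10 ± 0.23, adjusted p = 0.0342). These were the 4 goblet cell genes of 24 that rose, and 13 did when adjusted over the list alone. Goblet cell genes had a median log2 change of 0.77 (camera adjusted p = 7.14e-12, adjusted p = 0.147 with an estimated correlation). Gsr, which regenerates glutathione, rose 4.15-fold (2.05 ± 0.22, adjusted p = 0.00188), from 132 ± 15.0 to 597 ± 49.9. Reg3g, an antibacterial lectin, rose at least 5.77-fold (2.53 ± 0.55, adjusted p = 0.0377), and Itln1, a lectin that binds microbial sugars, rose 4.38-fold (2.13 ± 0.33, adjusted p = 0.00991). Il33, an alarm cytokine of epithelia, rose 2.67-fold (1.42 ± 0.24, adjusted p = 0.013), and Hyou1, a chaperone of the endoplasmic reticulum, rose 2.67-fold (1.42 ± 0.25, adjusted p = 0.015). Kdelr3, a receptor that returns proteins to the reticulum, was 2.36-fold (-1.24 ± 0.22, adjusted p = 0.015) lower. Of 37 secretory genes of the reticulum Hyou1 was the 1 that rose and Kdelr3 the 1 that fell, 2 and 1 adjusted over the list alone. Secretory genes had a median log2 change of 0.24 (camera adjusted p = 0.00685, adjusted p = 0.595 with an estimated correlation), with a median of 0.14 without PN14 replicate 3, and the call ended without that array (the highest adjusted p with 1 array left out, 0.0508). The defence lists did not pass: innate genes had a median log2 change of 0.05 (camera adjusted p = 0.351), inflammatory genes 0.14 (camera adjusted p = 0.14) and interferon response genes 0.04 (camera adjusted p = 0.468). Of 33 cell junction genes 3 rose, 6 adjusted over the list alone. Junction genes had a median log2 change of 0.30 (camera adjusted p = 0.00013, adjusted p = 0.592 with an estimated correlation), with a median of 0.51 without PN14 replicate 2. Those called included Epcam at 3.5-fold (1.81 ± 0.39, adjusted p = 0.0389). Of 56 cell cycle genes only Rrm2, a subunit of ribonucleotide reductase, rose, at 1.92-fold (0.94 ± 0.22, adjusted p = 0.0491), and 9 did when adjusted over the list alone. Cell cycle genes had a median log2 change of 0.27 (camera adjusted p = 0.000182, adjusted p = 0.614 with an estimated correlation).

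Of 29 fibroblast and stroma genes 6 fell from PN14 to PN20, and 19 did when adjusted over the list alone. Stromal genes had a median log2 change of -0.70 (camera adjusted p = 1.68e-15, adjusted p = 0.147 with an estimated correlation). Those called included Mfap4, a protein of elastic fibres, at 3.25-fold (-1.70 ± 0.28, adjusted p = 0.0119), and Fn1, fibronectin, at 2.13-fold (-1.09 ± 0.19, adjusted p = 0.0159). Of 20 endothelium and mural cell genes 4 fell, 11 adjusted over the list alone. Endothelial and mural genes had a median log2 change of -0.65 (camera adjusted p = 2.6e-07, adjusted p = 0.478 with an estimated correlation). Those called included the smooth muscle genes Myh11 at 3.95-fold (-1.98 ± 0.29, adjusted p = 0.00787) and Tagln at 3.73-fold (-1.90 ± 0.42, adjusted p = 0.0423). Myl9, a light chain of smooth muscle myosin, fell 5.3-fold (-2.41 ± 0.37, adjusted p = 0.00968). Ccn2, a matrix protein, fell 4.1-fold (-2.04 ± 0.23, adjusted p = 0.00188). Of 24 skeletal muscle genes 1, Des, fell (at least 3.07-fold, -1.62 ± 0.27, adjusted p = 0.013), and 13 did when adjusted over the list alone. Muscle genes had a median log2 change of -1.71 (camera adjusted p = 1.52e-11, adjusted p = 0.494 with an estimated correlation). Desmin is also made by smooth muscle.

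In this step limma called 173 genes, 81 higher and 92 lower (46.8% higher, against 26.6% with scaling to the median of all probe sets), and the groups did not overlap for 30.3% of genes, where chance gives 10%. Genes that were higher in both steps numbered 9, against 3.48 for independent lists, and 8 were lower in both, against 2.34. The steps share the PN14 arrays, which by chance favours genes that go up and then down or down and then up (10 and 8 genes, against 3.96 and 2.06). The count was 100 without PN9 replicate 1, 268 without PN9 replicate 2, 21, 59 and 88 without PN14 replicates 1, 2 and 3, 30, 11 and 30 without PN20 replicates 1, 2 and 3, and 109 and 670 without Klf4CN replicates 1 and 3. It was 33 by the ordinary test, 101 with the actin ratio and 77 with sex as a covariate. Of the 22 genes of this text that the naming rule gives for this comparison and that passed, 5 passed whichever array was left out, and the calls lost were 16 (without PN20 replicate 2), 14 (without PN14 replicate 1), 13 (without PN20 replicates 1 or 3), 9 (without PN14 replicate 2), 7 (without PN9 replicate 1 or PN14 replicate 3) and 4 (without Klf4CN replicate 1).

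Over the whole interval from PN9 to PN20 the goblet cell, membrane mucin, cell junction and transport lists rose. Of 24 goblet cell genes 19 rose, 21 adjusted over the list alone. Goblet cell genes had a median log2 change of 1.74 (camera adjusted p = 1.68e-13, adjusted p = 0.147 with an estimated correlation). Those called included Muc5ac at 31.5-fold (4.98 ± 0.50, adjusted p = 2.97e-05), Gcnt3 at 15.4-fold (3.95 ± 0.28, adjusted p = 2.23e-06) and Tspan8 at 15.2-fold (3.93 ± 0.41, adjusted p = 3.49e-05). Gp2 went from 27.5 ± 10.8 to 2530 ± 198, or 59.5-fold (5.90 ± 0.49, adjusted p = 1.23e-05), and Slc5a1 rose 43.8-fold (5.45 ± 0.39, adjusted p = 2.23e-06). Olfm4, a secreted glycoprotein, rose 17.4-fold (4.12 ± 0.58, adjusted p = 0.000259), and Slc44a4, a choline transporter-like protein, rose 16.4-fold (4.04 ± 0.38, adjusted p = 2.53e-05). Of 16 membrane mucin genes 8 rose, 11 adjusted over the list alone. Membrane mucin genes had a median log2 change of 0.85 (camera adjusted p = 0.000241, adjusted p = 0.489 with an estimated correlation). Those called included Muc1 at 5.16-fold (2.37 ± 0.26, adjusted p = 5.15e-05). Of 33 cell junction genes 16 rose, 17 adjusted over the list alone. Junction genes had a median log2 change of 0.73 (camera adjusted p = 7.47e-07, adjusted p = 0.526 with an estimated correlation). Those called included Cldn7 at 9.14-fold (3.19 ± 0.33, adjusted p = 3.46e-05). Of 29 ion and water transport genes 12 rose and 2 fell, also adjusted over the list alone. Transport genes had a median log2 change of 0.57 (camera adjusted p = 0.000241, adjusted p = 0.498 with an estimated correlation). Those called included Aqp4 at 17.9-fold (4.16 ± 0.51, adjusted p = 0.000108). Of 9 mucosal keratins 4 rose, with 5 higher and 1 lower adjusted over the list alone. Mucosal keratins had a median log2 change of 0.73 (camera adjusted p = 0.0128, adjusted p = 0.591 with an estimated correlation). Those called included Krt23 by at least 8.6-fold (3.10 ± 0.36, adjusted p = 6.2e-05) and Krt13 at 3.97-fold (1.99 ± 0.48, adjusted p = 0.00824). The call of the keratin list ended without PN9 replicate 3 (the highest adjusted p with 1 array left out, 0.0669).

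Of 34 lipid and cholesterol synthesis genes 14 rose from PN9 to PN20, with 19 higher and 1 lower adjusted over the list alone. Lipid synthesis genes had a median log2 change of 0.92 (camera adjusted p = 8.44e-06, adjusted p = 0.526 with an estimated correlation). Those called included Cyp51 at 8.39-fold (3.07 ± 0.29, adjusted p = 2.53e-05). Of 9 gland markers 2 rose, with 5 higher and 1 lower adjusted over the list alone, and that list did not pass (median log2 change 1.10, camera adjusted p = 0.0833). Of 39 interferon response genes 14 rose and 1 fell, 16 and 1 adjusted over the list alone. Interferon response genes had a median log2 change of 0.80 (camera adjusted p = 3.69e-05, adjusted p = 0.592 with an estimated correlation). Those called included Irf1, an interferon regulatory factor, at 4.77-fold (2.26 ± 0.35, adjusted p = 0.000552) and Rtp4 at 5.21-fold (2.38 ± 0.33, adjusted p = 0.000235). Of 30 innate receptor and antimicrobial genes 10 rose, 10 adjusted over the list alone. Innate defence genes had a median log2 change of 0.51 (camera adjusted p = 0.000537, adjusted p = 0.478 with an estimated correlation). Those called included Reg3g by at least 13.2-fold (4.02 ± 0.55, adjusted p = 0.000222) and Pigr at 12.6-fold (3.65 ± 0.49, adjusted p = 0.000205). Of 37 endoplasmic reticulum secretory genes 19 rose and 2 fell, 24 and 3 adjusted over the list alone. Secretory genes had a median log2 change of 0.62 (camera adjusted p = 8.44e-06, adjusted p = 0.494 with an estimated correlation). Dnajb9, a co-chaperone, was 3.02-fold (1.60 ± 0.21, adjusted p = 0.000201) higher and Kdelr3 4-fold (standard error 0.22 on the log2 scale, adjusted p = 4.6e-05) lower. Igf2 was 13.6-fold (-3.77 ± 0.27, adjusted p = 2.23e-06) lower, Mdk, a growth factor of developing tissue, 6.7-fold (-2.75 ± 0.34, adjusted p = 0.000104) lower, and Col11a1, a fibrillar collagen gene, 6.93-fold (-2.79 ± 0.42, adjusted p = 0.000425) lower.

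Markers of other cell types fell or rose beside these groups. Of 29 fibroblast and stroma genes 23 fell from PN9 to PN20, 25 adjusted over the list alone. Stromal genes had a median log2 change of -1.30 (camera adjusted p = 5.06e-15, adjusted p = 0.147 with an estimated correlation). Those called included Col12a1 at 5.57-fold (-2.48 ± 0.34, adjusted p = 0.000224) and Lox, a collagen crosslinking enzyme, at 3.58-fold (-1.84 ± 0.30, adjusted p = 0.000658). Of 20 endothelium and mural cell genes 13 fell, 14 adjusted over the list alone. Endothelial and mural genes had a median log2 change of -0.88 (camera adjusted p = 2.78e-07, adjusted p = 0.478 with an estimated correlation). Those called included Myh11 at 5.43-fold (-2.44 ± 0.29, adjusted p = 7.63e-05). Of 27 lens and retina genes 4 rose, 4 adjusted over the list alone. Lens and retina genes had a median log2 change of 1.22 (camera adjusted p = 0.00494, adjusted p = 0.682 with an estimated correlation), with a median of 0.65 without PN9 replicate 2. Those called included Sag, the visual arrestin, at 6.85-fold (2.78 ± 0.67, adjusted p = 0.00824), and the call of the lens and retina list ended without PN9 replicate 2 (the highest adjusted p with 1 array left out, 0.137). Skeletal muscle genes had a median log2 change of 0.45 with 2 higher and 2 lower, and the list did not pass (camera adjusted p = 0.578). The mean actin ratio fell from 34.9 to 12.7.

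Between PN9 and PN20 limma called 3406 genes, 1897 higher and 1509 lower, and 1725 of the calls were at least 2-fold. The groups did not overlap for 43.6% of genes, where chance gives 10%. Of the calls 55.7% were higher, but with the values as deposited 1538 were higher and 2241 lower (40.7% higher), and that scaling moved the median of all genes by -0.13 on the log2 scale. The count was 2225 without PN9 replicate 1, 2022 without PN20 replicate 1, 2110 without PN20 replicate 3 and 573 with the actin ratio as a covariate. Of the 62 genes of this text that the naming rule gives for this comparison and that passed, 58 passed whichever array was left out, and the calls lost were 4 (without PN9 replicate 2 or PN20 replicates 1 or 3), 3 (without PN9 replicate 1 or PN20 replicate 2), 2 (without PN14 replicates 1, 2 or 3) and 1 (without Klf4CN replicates 1 or 2). A moderated F test over the 3 wild-type ages called 2799 genes, of which 1237 rose in both steps, 934 fell in both, 331 rose and then fell, and 297 fell and then rose, by the signs of their mean changes. That count was 1573 without PN9 replicate 1, 1682, 1788 and 1666 without PN20 replicates 1, 2 and 3, and 416 with the actin ratio as a covariate.

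**Figure D1:**
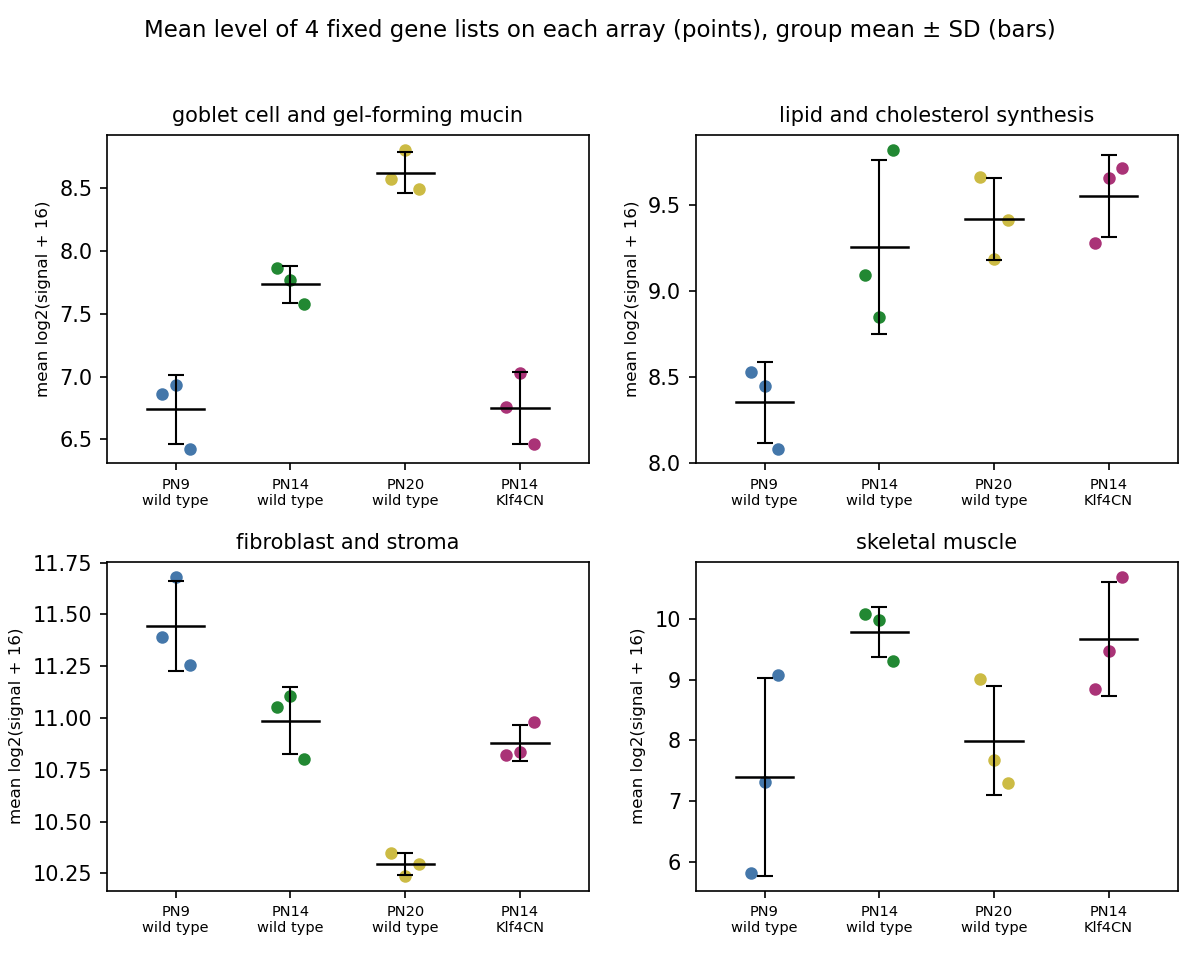
Mean log2(signal + 16) of the genes of 4 lists on each of the 12 arrays (points, y axis) by group (x axis), with group mean ± SD (bars, n = 3). Goblet cell genes rose from PN9 to PN20 by a median of 1.74 and stromal genes fell by 1.30 on the log2 scale, while skeletal muscle genes spread over 3.25 log2 units within PN9.

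At PN14 goblet cell genes were lower in the samples labelled Klf4CN than in wild type, as were the water channel gene Aqp5 and the keratins Krt78 and Krt80. Muc5ac read 3.44 ± 1.53 in Klf4CN, with no Present call on its 3 arrays, against 821 ± 279.6 in wild type, and was at least 37.4-fold (log2 change -5.37 ± 0.50, adjusted p = 0.000263) lower. Muc5b, another gel-forming mucin, was at least 5.26-fold (-2.40 ± 0.28, adjusted p = 0.00145) lower, Gcnt3 3.48-fold (-1.80 ± 0.28, adjusted p = 0.0236) lower, and Bcas1 3.11-fold (-1.64 ± 0.27, adjusted p = 0.0253) lower. With Galnt12, an enzyme that starts mucin sugar chains and was singled out after its values were seen, these were the 5 of 24 goblet cell genes that fell. When adjusted over the list alone 10 fell. Goblet cell genes had a median log2 change of -0.63 (camera adjusted p = 5.38e-17, adjusted p = 0.147 with an estimated correlation), and 23 of the 24 changes lay below 0. The median was the same, -0.63, with the 5 genes that had no Present call in Klf4CN at their bound. Aqp5 read 202 ± 108 against 2779 ± 1106 and was 13.2-fold (-3.72 ± 0.37, adjusted p = 0.000351) lower. Of the 29 ion and water transport genes it was the 1 that fell, and the list did not pass (camera adjusted p = 0.173).

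**Figure D2:**
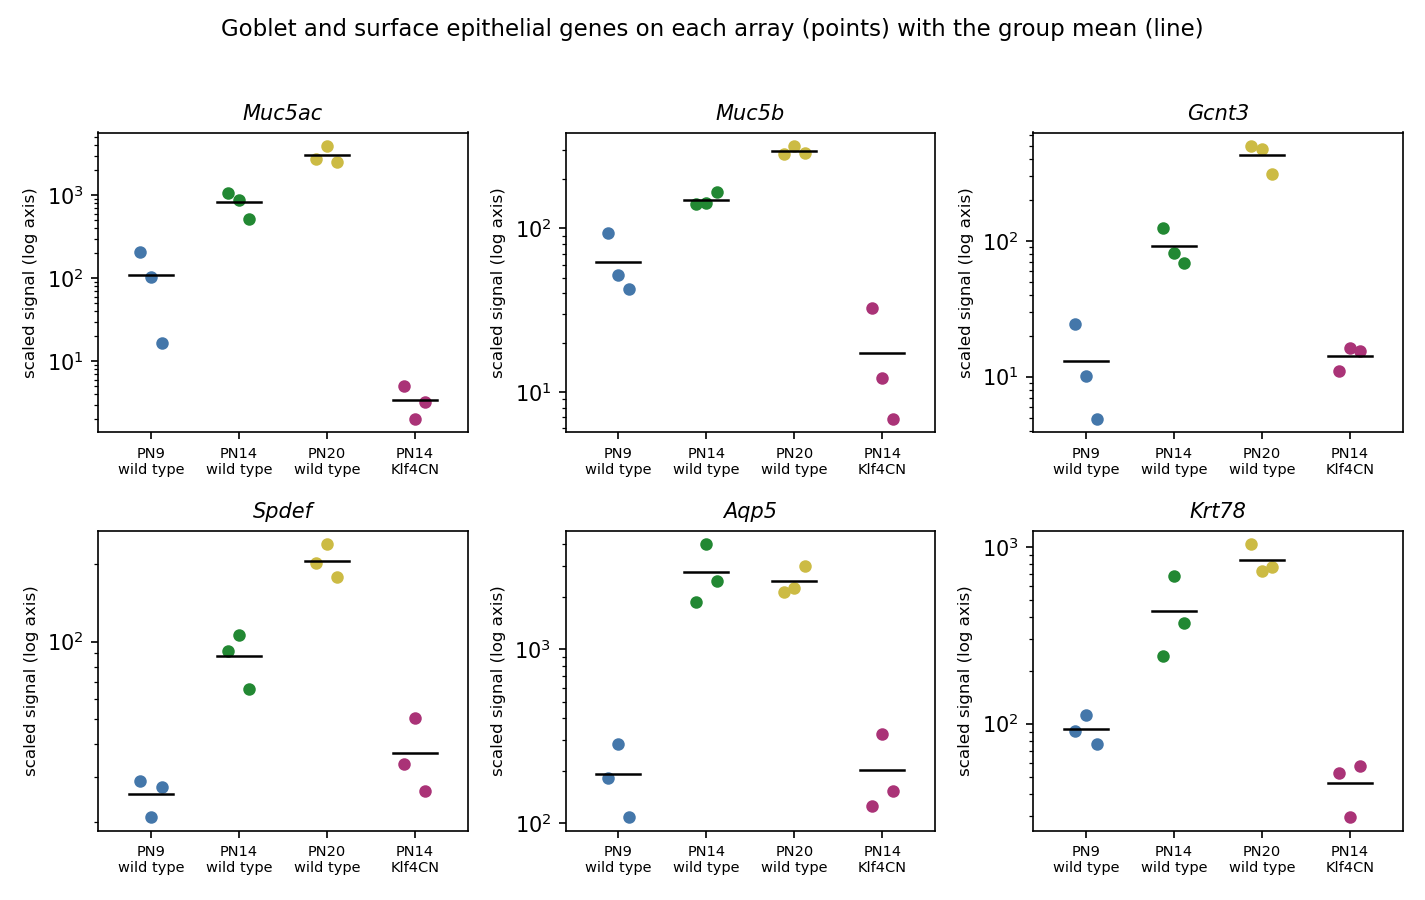
Scaled signal (log y axis) of Muc5ac, Muc5b, Gcnt3, Spdef, Aqp5 and Krt78 on each of the 12 arrays (points) by group (x axis), with the group mean (line, n = 3). Muc5ac stood at 3055 at PN20 and at 3.44 in Klf4CN, and Aqp5 at 2779 in wild type and 202 in Klf4CN at PN14; Spdef did not pass in Klf4CN (adjusted p = 0.149).

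Of 9 mucosal keratins 2 were lower in Klf4CN, Krt78 at 6.78-fold (-2.76 ± 0.31, adjusted p = 0.00129) and Krt80 at 3.38-fold (-1.76 ± 0.28, adjusted p = 0.0236), and 3 were when adjusted over the list alone. Mucosal keratins had a median log2 change of -0.37 (camera adjusted p = 0.000324, adjusted p = 0.498 with an estimated correlation), with a median of -0.19 without PN14 replicate 2, -0.62 without Klf4CN replicate 2 and 0.09 without Klf4CN replicate 3. That list's call ended without Klf4CN replicate 3 (the highest adjusted p with 1 array left out, 0.0715). Lypd2, a surface protein of the Ly6 family, read 39.8 ± 64.7 against 1616 ± 1088 and was at least 35.6-fold lower (adjusted p = 0.0456), and Slc28a3, a nucleoside transporter, 4.59-fold (-2.20 ± 0.39, adjusted p = 0.0374) lower. Apol7a, an apolipoprotein L gene, was 3.44-fold (-1.78 ± 0.30, adjusted p = 0.026) lower and AW112010 4.85-fold (-2.28 ± 0.36, adjusted p = 0.0236) lower. The membrane mucins Muc4, at 1979 ± 2031 against 9006 ± 1638 (log2 change -2.76 ± 0.63, adjusted p = 0.145), and Muc16, at 35.8 ± 13.6 against 118 ± 31.6 (-1.37 ± 0.30, adjusted p = 0.114), did not pass. Of 16 membrane mucin genes limma and the ordinary test called 0 (2 higher and 3 lower at an unadjusted limma p under 0.05), with 1 higher and 3 lower adjusted over the list alone. The list did not pass either (median log2 change 0.10, camera adjusted p = 0.631). Of 12 corneal epithelium genes 0 passed with limma (4 lower and 1 higher at an unadjusted p under 0.05, and 0 by the ordinary test), and 3 were lower adjusted over the list alone. Corneal genes had a median log2 change of -0.66 (camera adjusted p = 0.00609, adjusted p = 0.556 with an estimated correlation), with a median of -0.15 without Klf4CN replicate 3. That call ended without Klf4CN replicate 3 (the highest adjusted p with 1 array left out, 0.181).

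Genes higher in Klf4CN included H2-DMb2, Il33 and Ccl8, of 2 immune lists. All 3 lost their call without PN14 replicate 1, 2 or 3 or Klf4CN replicate 2. H2-DMb2, which loads peptides onto class II molecules, was 4.22-fold (2.08 ± 0.33, adjusted p = 0.0236) higher, and it was the 1 class II gene of 11 that rose, with 3 adjusted over the list alone. Class II genes had a median log2 change of 0.43 (camera adjusted p = 4.16e-05, adjusted p = 0.24 with an estimated correlation), with a median of 0.67 without Klf4CN replicate 3. The cytokine Il33, at 2.51-fold (1.33 ± 0.24, adjusted p = 0.0385), and the chemokine Ccl8, at 2.54-fold (1.34 ± 0.25, adjusted p = 0.0445), were the 2 of 36 inflammatory genes that rose, with 5 adjusted over the list alone. Inflammatory genes had a median log2 change of 0.21 (camera adjusted p = 0.000838, adjusted p = 0.53 with an estimated correlation), with a median of 0.06 without PN14 replicate 3, 0.07 without Klf4CN replicate 1 and 0.41 without Klf4CN replicate 3. That list's call ended without Klf4CN replicate 1 (the highest adjusted p with 1 array left out, 0.0804). The innate defence list, with 1 of 30 genes higher and 2 adjusted over the list alone, did not pass (median log2 change 0.11, camera adjusted p = 0.138). The interferon response list (median 0.16, camera adjusted p = 0.145) and the lymphocyte list (0.14, camera adjusted p = 0.103) did not pass either. Wfdc18, a secreted protein of the whey acidic protein family, was 4.02-fold (2.01 ± 0.31, adjusted p = 0.0236) higher, Retnla, a resistin-like secreted protein, 3.45-fold (1.79 ± 0.33, adjusted p = 0.0391) higher, and Tafa2, a secreted chemokine-like protein, 3.38-fold (1.76 ± 0.24, adjusted p = 0.00818) higher. Cd209e, a C-type lectin, was at least 2.74-fold (1.60 ± 0.29, adjusted p = 0.0374) higher, and Tnc, a matrix protein found in healing and developing tissue, 2.67-fold (1.42 ± 0.24, adjusted p = 0.03) higher. Tfrc, the transferrin receptor, was 2.53-fold (1.34 ± 0.22, adjusted p = 0.0253) higher. Myeloid and mast cell markers had 0 of 24 genes called by limma or by the ordinary test (4 higher and 0 lower at an unadjusted limma p under 0.05), with a median log2 change of 0.26 (camera adjusted p = 0.0174, adjusted p = 0.487 with an estimated correlation), which was 0.11 without Klf4CN replicate 2, and the call ended without PN14 wild-type replicate 3 or Klf4CN replicate 2 (highest adjusted p with 1 array left out, 0.0695) and with the actin ratio as a covariate (median 0.20, adjusted p = 0.0759). Lens and retina genes had 0 of 27 called by limma or by the ordinary test (6 lower at an unadjusted limma p under 0.05) and a median of -1.09 (camera adjusted p = 0.000595, adjusted p = 0.614 with an estimated correlation), which was -0.73 without PN14 replicate 3 and 0.20 without Klf4CN replicate 2. This call ended without Klf4CN replicate 2 (adjusted p = 0.651, the highest with 1 array left out) and with the actin ratio as a covariate (median -0.10, adjusted p = 0.381). Lipid synthesis genes had 0 of 34 called by limma or by the ordinary test (3 higher and 1 lower at an unadjusted limma p under 0.05, and 0 adjusted over the list alone). They had a median log2 change of 0.29 (camera adjusted p = 0.0174, adjusted p = 0.682 with an estimated correlation). It was 0.16, 0.11 and 0.49 without PN14 replicates 1, 2 and 3, and 0.14 without Klf4CN replicate 3. The call ended without PN14 replicates 1 or 2 or Klf4CN replicates 2 or 3 (highest adjusted p with 1 array left out, 0.46). Gland markers had 0 of 9 called by limma or by the ordinary test (1 higher at an unadjusted limma p under 0.05, and 1 adjusted over the list alone). Gland markers had a median log2 change of 0.79 (camera adjusted p = 0.00555, adjusted p = 0.526 with an estimated correlation). It was 0.26 without PN14 replicate 2 and 1.26 without Klf4CN replicate 1. The call ended without PN14 replicate 2 or Klf4CN replicate 3 (highest adjusted p with 1 array left out, 0.348).

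In all, limma called 30 genes in Klf4CN, 12 higher and 18 lower, all at least 2-fold, and the ordinary test called 0 (lowest adjusted p 0.0638), with 1195 and 1245 genes at an unadjusted p under 0.05. The groups did not overlap for 13.1% of genes, where chance gives 10%, and 40% of the calls were higher, against 27.3% with scaling to the median of all probe sets. The count was 14 without PN9 replicate 1, 8, 4 and 11 without PN14 wild-type replicates 1, 2 and 3, 19, 17 and 17 without PN20 replicates 1, 2 and 3, 17, 19 and 58 without Klf4CN replicates 1, 2 and 3, 9 with sex and 5 with the actin ratio as a covariate. Of the 22 genes of this text that the naming rule gives for this comparison and that passed, 4 passed whichever array was left out, and the calls lost were 18 (without PN14 replicate 2), 14 (without PN14 replicate 1), 13 (without PN14 replicate 3), 10 (without PN9 replicate 1 or Klf4CN replicate 2), 9 (without Klf4CN replicate 1), 7 (without PN20 replicates 1, 2 or 3), 6 (without PN9 replicate 3), 4 (without Klf4CN replicate 3) and 1 (without PN9 replicate 2).

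**Figure D3:**
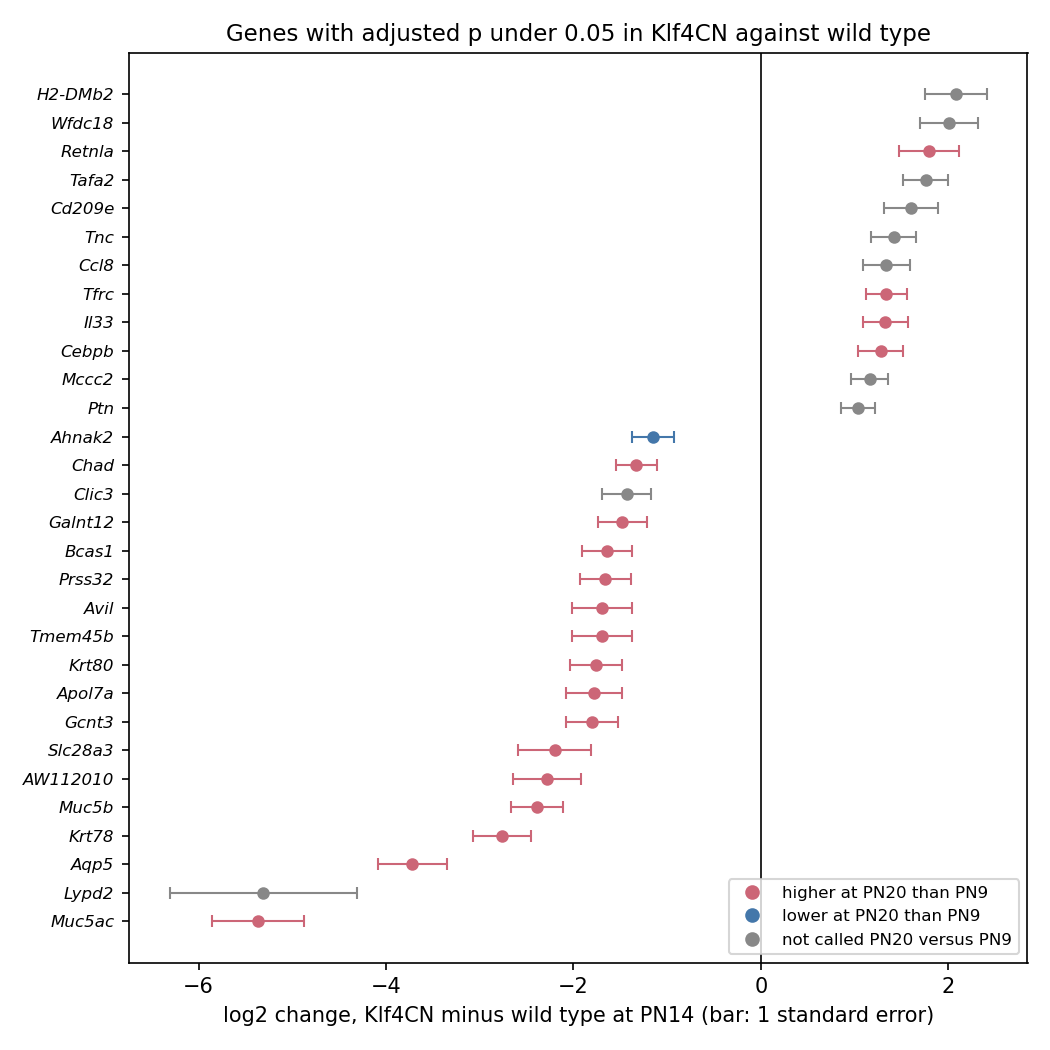
Log2 change (x axis, bars of 1 standard error) of the 30 genes that limma called in Klf4CN against wild type at PN14 (y axis), coloured by their call from PN9 to PN20. Of the 18 lower genes, 15 were higher at PN20 than at PN9.

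Of the 18 genes lower in Klf4CN, 15 had risen in wild type from PN9 to PN20, where independent lists would share 2.41 (two-sided Fisher's exact test p = 4.18e-11, adjusted p = 1.67e-10 over 4 tests). By the fixed rule they included Muc5ac, Aqp5, Krt78, AW112010 and Slc28a3. From PN9 to PN20 AW112010 was 13.2-fold (3.73 ± 0.36, adjusted p = 2.53e-05) higher and Slc28a3 10.1-fold (3.34 ± 0.39, adjusted p = 8.14e-05) higher. Of the 15, 9 had a lower mean signal in Klf4CN than in wild type at PN9 and 6 a higher one, a count made after the values were seen and not tested. The extremes on the log2 scale were Muc5ac, at 3.44 ± 1.53 and 109.7 ± 96.0, and Apol7a, at 203 ± 88.2 and 73.1 ± 6.99 (SD, n = 3). Of the 12 genes higher in Klf4CN, 4 had also risen, Il33, Retnla, Tfrc and Cebpb, a transcription factor of the C/EBP family, against 1.61 for independent lists (Fisher's exact test p = 0.0654, adjusted p = 0.131). Ahnak2, a large scaffold protein, was 2.22-fold (-1.15 ± 0.22, adjusted p = 0.0492) lower in Klf4CN and 1.86-fold (-0.90 ± 0.22, adjusted p = 0.00909) lower at PN20 than at PN9. It was the 1 gene lower in both, against 1.92 for independent lists (Fisher's exact test adjusted p = 0.713), and 0 genes had fallen with age and were higher in Klf4CN, against 1.28 (Fisher's exact test adjusted p = 0.713). The overlap of 15 genes was between 4 and 17 with 1 array left out, and 5 with the actin ratio as a covariate. It also fell with sex as a covariate and with the median of all probe sets, and rose with array weights and at unadjusted p with 2-fold. Fisher's exact test takes genes as independent, and both comparisons share a variance estimate per gene, so its p measures no spread between samples.

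Taken as whole sets, the genes that changed with age had small medians in Klf4CN. The 1897 genes that rose from PN9 to PN20 had a median log2 change of 0.08 in Klf4CN (camera p = 0.013, p = 0.623 with an estimated correlation), and 40.9% lay below 0. This median was -0.08 without Klf4CN replicate 2 and -0.09 with the actin ratio as a covariate. The 1509 genes that fell had a median of -0.12 (camera p = 3.55e-06, p = 0.259 with an estimated correlation), and 67.2% lay below 0. A score per array, the mean log2 level of the genes that rose less that of the genes that fell, was -0.428 ± 0.229 at PN9, 0.919 ± 0.117 at PN14, 1.854 ± 0.057 at PN20 and 1.091 ± 0.427 in Klf4CN (SD, n = 3). The genes were picked by the comparison of PN20 with PN9, so the order of PN9 and PN20 is given by construction. Levels at PN14 picked no gene, but a group outside the picking is expected to lie between the picked extremes, as Klf4CN also did. The place of wild type at PN14 between them is therefore no separate evidence of a course with age. The score of Klf4CN exceeded that of wild type at PN14 by 0.172 (exact two-sided permutation test p = 0.5, where 3 arrays against 3 cannot go below 0.1). The difference was -0.0339 without Klf4CN replicate 2, 0.385 without Klf4CN replicate 3 and -0.146 with the actin ratio as a covariate.

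**Figure D4:**
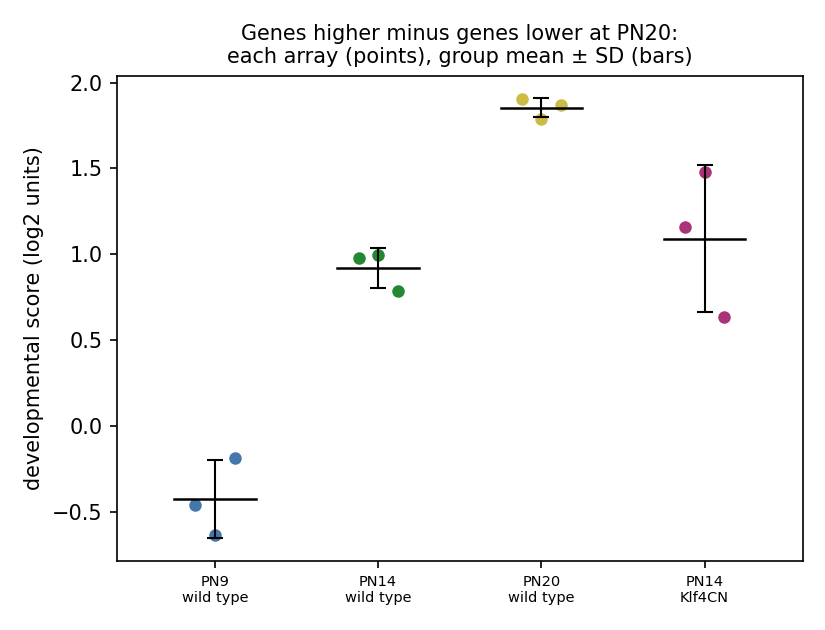
Developmental score (y axis, log2 units) of each of the 12 arrays (points) by group (x axis), with group mean ± SD (bars, n = 3). The Klf4CN arrays at 1.156, 1.481 and 0.635 spread around the wild-type arrays of the same age, at 0.978, 0.995 and 0.784.

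In the authors' deposited table a total of 4105 probe sets carry a code for 1 or more comparisons, assigned by a rule of Present calls, fold and pairwise comparisons. That table assigns 1417 probe sets between PN9 and PN14 (810 higher, 607 lower), 784 between PN14 and PN20 (288 and 496), 3261 between PN9 and PN20 (1479 and 1782) and 223 in Klf4CN (122 and 101). Of the 223 in the authors' deposited table, 112 are also assigned to a comparison of ages, 44 are higher at PN20 than at PN9 and lower in Klf4CN, 28 are higher in both, 9 are lower in both and 3 are lower at PN20 and higher in Klf4CN. With limma on all kept probe sets, an adjusted p under 0.05 in the same direction was found for 61.7%, 24.5%, 89.4% and 7.17% of the probe sets that the authors' deposited table assigns, in that order. For Klf4CN these were 16 of 223 probe sets, and 216 had an unadjusted limma p under 0.05. The fold, Present and non-overlap parts of the rule, with the deposited pairwise sums, gave the deposited code for 45100 of 45101 probe sets.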

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

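The tests of the goblet, muscle and stromal patterns were chosen after those results were seen; the counts of other splits of the arrays were planned. Control probe sets that no comparison uses stood out on Klf4CN replicate 3. Its 18S ribosomal RNA control probe sets had a geometric mean of 12150, against 6514 on the highest wild-type array, and its hybridisation controls one of 4950, against 3147. This array also had the 2 lowest correlations with its replicates (0.9317 and 0.9211). Outliers were not tested, since each group has 3 arrays and the rule used needs 4.

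Goblet cell genes were lower in Klf4CN, with a median log2 change of -0.63. All 3 Klf4CN arrays and 2 of the 3 wild-type arrays at PN14 had high Xist. With sex as a covariate the median was -0.619 (standard error of the list's mean change 0.193), which argues against sex as the cause. Without Klf4CN replicate 3 the median was -0.608 (standard error of the list's mean change 0.183), which argues against that array as the cause. Differences of litter, genetic background and capture between genotypes could contribute and stay open, as does the candidate biological explanation, an effect of the genotype, either through fewer goblet cells or through less expression in each, which these arrays cannot separate.

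Skeletal muscle genes were highest at PN14. Muscle tissue carried into the captures is a candidate source, as a hypothesis: within groups the 24 genes moved together (mean pairwise correlation 0.687, against a median of 0.0839 and a 95th percentile of 0.197 in 10000 random lists), and within PN9 they spread over 3.25 log2 units, against 2.39 between PN9 and PN14. The most abundant, Myh1, read 1065 ± 1570, 8701 ± 1916 and 3196 ± 2558 at PN9, PN14 and PN20 and 9463 ± 3671 in Klf4CN (SD, n = 3), and 12 of the 24 were Present on every wild-type array. Maturation of muscle fibres as the whole cause would lower Myh3, the embryonic myosin, which read 4.04 higher on the log2 scale at PN14 than at PN9 (standard error 1.07), weak evidence from 1 gene: its call was lost without PN9 replicate 1 (2.78, adjusted p = 0.148), PN9 replicate 2 (4.42, 0.0637), PN14 replicate 1 (3.81, 0.122), PN14 replicate 2 (3.78, 0.115) or PN20 replicate 2 (4.04, 0.0524) and with the actin ratio (2.70, 0.26). Laser capture aims to exclude muscle, and a change in how tissue was captured at each age may remain beside any biological effect of age, which was not tested.

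Stromal genes fell by a median of -1.30 from PN9 to PN20. With the actin ratio as a covariate it was -1.25 (standard error of the list's mean change 0.176). The ratio did not overlap between these ages, so RNA quality stays open. A smaller share of stroma, which laser capture aims to exclude, could explain part or all of the fall: all 29 genes were Present on every wild-type array, 1 of them (Thy1) is also in the lymphocyte list, and Col3a1, the most abundant, read 15820 ± 3129, 13260 ± 2471 and 11090 ± 1147 at PN9, PN14 and PN20 (SD, n = 3). The members' log2 changes had an SD of 0.597 against a root mean square standard error of 0.246 (0.631 against 0.277 in the 14 of lower level at PN9), which excludes nothing, since probe sets can respond unequally to the same change and other cells could make part of the signal. A biological fall in stromal expression with age stays open beside it, since within-group correlation (0.18, against a median of 0.128 and a 95th percentile of 0.236 in random lists) did not decide.

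Other splits of the arrays were counted for each number of genes called. Between 2 groups of 3 arrays there are 10 splits, too few for a share under 0.05. In each comparison 1 of the 10, the real one, called as many: 969 genes between PN9 and PN14 (highest other 2), 173 between PN14 and PN20 (highest other 0), 3406 between PN9 and PN20 (highest other 0) and 30 in Klf4CN (highest other 0). For the 3 ages, 1 of 100 splits (drawn from 280), the real one, called as many as 2799 genes (highest other 1076). That argues against chance as the source of this count. It does not separate age from what moved with age, such as the actin ratio.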

How the results depend on the processing

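The settings with values as deposited, the median of all probe sets, sex, the actin ratio and without 2 arrays of high added control RNA were chosen after the data were seen; the others were planned, and the other deposited table could not differ. The cause was not tested for any change below, apart from thresholds and sample numbers that change a count by construction. Of 171 pairs of a named gene and a comparison, 151 passed, 0 of these reversed under any alternative and 68 passed under every one. The medians of the 67 list calls kept their sign under every scaling. For dim genes the offset pulls folds toward 1.

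Genes called between PN9 and PN14 (969) became 2945 with array weights, 434 with the ordinary test, 565 with a 2-fold minimum, 1996 at adjusted p under 0.1, 566 with the median of all probe sets, 587 with sex, 133 with the actin ratio and 1536 without the 2 arrays. Between PN14 and PN20 (173) they became 106 with the mean of a gene's probe sets, 106 with no trend, 1415 with array weights, 33 with the ordinary test, 617 at adjusted p under 0.1, 405 at unadjusted p with 2-fold, 110 with the replicate block, 1198 with only the samples compared, 94 with the median of all probe sets, 77 with sex, 101 with the actin ratio and 1012 without the 2 arrays. Between PN9 and PN20 (3406) they became 5210 probe sets when all were counted, 5721 genes with array weights, 1725 with 2-fold, 1828 at unadjusted p with 2-fold and 573 with the actin ratio. For any age (2799) they became 4278 probe sets when all were counted, 5734 genes with array weights, 1791 with 2-fold and 416 with the actin ratio. In Klf4CN (30) they became 19 with offset 1, 17 probe sets when all were counted, 18 genes with the mean of a gene's probe sets, 19 with no trend, 221 with array weights, 0 with the ordinary test (1245 at an unadjusted p under 0.05), 193 at unadjusted p with 2-fold, 9 with only the samples compared, 11 with the median of all probe sets, 9 with sex, 5 with the actin ratio and 139 without the 2 arrays.

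The Klf4 difference in Klf4CN (0.72) passed with array weights, at 0.9332, and Klf4 from PN14 to PN20 (0.40) reversed to -0.3092 with the mean of its probe sets. Of 67 list calls 0 were left with an estimated correlation and 34 with fry. The median of the genes higher at PN20 (0.08) lost its camera call at 0.0407 with quantile normalization, 0.0578 with the mean of probe sets, 0.0311 with 2-fold, 0.0303 at unadjusted p with 2-fold, 0.0803 with an estimated correlation, 0.0381 with values as deposited and 0.0524 with the median of all probe sets, and reversed to -0.0903 with the actin ratio; that of the lower genes lost it at -0.122 with an estimated correlation. The overlap of 15 genes became 40 with array weights, 53 at unadjusted p with 2-fold, 8 with the median of all probe sets, 8 with sex and 5 with the actin ratio, and the score difference (0.172) reversed to -0.146 with the actin ratio.

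With 1 array left out the counts ranged from 275 to 1964 (PN9 to PN14), 11 to 670 (PN14 to PN20), 2022 to 4220 (PN9 to PN20), 4 to 58 (Klf4CN) and 1573 to 3926 (any age). Of the arrays named in the report for each count, the lowest came without PN9 replicate 1, PN20 replicate 2, PN20 replicate 1, PN14 wild-type replicate 2 and PN9 replicate 1. The Klf4 difference ranged from 0.5725 to 0.8905, the list calls from 61 to 71, the median of genes higher at PN20 from -0.079 (without Klf4CN replicate 2) to 0.255, that of lower genes from -0.178 to -0.076, the overlap from 4 to 17 and the score difference from -0.0339 (without Klf4CN replicate 2) to 0.385. The lens and retina median in Klf4CN (-1.09) ranged from -1.39 (without Klf4CN replicate 3) to 0.195, reversed (without Klf4CN replicate 2).

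Of the 67 list calls these ended: 3 with offset 1 (PN14 to PN20 keratin, PN9 to PN20 class II and hair follicle), 1 with offset 64 (PN9 to PN20 class II), 2 with quantile normalization (PN9 to PN14 cornification, PN9 to PN20 hair follicle), 10 with a filter at the 60th percentile (PN9 to PN14 keratin, basal, cornification, myeloid and hair follicle, PN14 to PN20 keratin and respiratory chain, PN9 to PN20 class II, epithelial factors and hair follicle), 6 with genes Present on at least 3 arrays (PN9 to PN14 basal, cornification and gland, PN14 to PN20 keratin, PN9 to PN20 class II and hair follicle), 2 with the mean of a gene's probe sets (PN9 to PN14 cornification, PN14 to PN20 respiratory chain), 5 with array weights (PN9 to PN14 cornification, PN9 to PN20 class II, Klf4CN corneal, lipid and gland), 2 with values as deposited (PN9 to PN14 cornification, PN9 to PN20 hair follicle), 1 with sex (PN14 to PN20 respiratory chain), 11 with the actin ratio (PN9 to PN14 cornification, ribosomal, endothelium and myeloid, PN14 to PN20 ribosomal and respiratory chain, PN9 to PN20 class II, ribosomal and hair follicle, Klf4CN myeloid and lens and retina) and 9 without the 2 arrays (PN9 to PN14 cornification and lens and retina, PN9 to PN20 class II, epithelial factors and lens and retina, Klf4CN keratin, corneal, lipid and gland).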

Other observations

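The tests of lists here were planned, and those with the actin ratio or with values as deposited were chosen after the data were seen. Among clock genes from PN9 to PN20 6 of 16 rose and 1 fell (7 and 2 adjusted over the list alone). Clock genes had a median log2 change of 0.35 (camera adjusted p = 0.0139, adjusted p = 0.509 with an estimated correlation). Nr1d2 was 3.62-fold (1.86 ± 0.32, adjusted p = 0.000973) higher, Per3 2.62-fold (1.39 ± 0.22, adjusted p = 0.00055) higher and Clock 2.23-fold (1.16 ± 0.28, adjusted p = 0.00828) higher. The hour of collection is not given in the labels.

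Among ribosomal protein genes from PN9 to PN20 8 of 21 fell (10 adjusted over the list alone), with Rps15 3.9-fold (-1.96 ± 0.38, adjusted p = 0.00202) lower. Ribosomal protein genes had a median log2 change of -0.57 (camera adjusted p = 4.95e-06, adjusted p = 0.591 with an estimated correlation), with a median of -0.36 without PN9 replicate 2. With the actin ratio as a covariate the median was -0.28 and the call ended (adjusted p = 0.0616, against a highest of 0.00017 with 1 array left out). The mean actin ratio itself fell from 34.9 to 12.7. Among respiratory chain genes 5 of 36 rose (6 adjusted over the list alone) from PN9 to PN14. Respiratory chain genes had a median log2 change of 0.25 (camera adjusted p = 0.00473, adjusted p = 0.614 with an estimated correlation), with a median of 0.14 without PN9 replicate 3, and the call ended without that array (the highest adjusted p with 1 array left out, 0.122). From PN14 to PN20 limma and the ordinary test called 0 of 36 (6 lower at an unadjusted limma p under 0.05, and 0 adjusted over the list alone). Respiratory chain genes had a median log2 change of -0.17 (camera adjusted p = 0.0376, adjusted p = 0.707 with an estimated correlation), with a median of -0.10 without PN20 replicate 3, and this call ended without PN14 replicates 1 or 3 or PN20 replicate 3 (highest adjusted p with 1 array left out, 0.256), with the actin ratio (median -0.11, adjusted p = 0.0804) and with sex (median -0.11, adjusted p = 0.0823). From PN9 to PN20 7 of 36 rose and 2 fell (7 and 3 adjusted over the list alone), with Ndufa4 3.02-fold (1.60 ± 0.29, adjusted p = 0.00129) higher, and the list did not pass (median log2 change 0.09, camera adjusted p = 0.468).

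Among Wnt genes from PN9 to PN20 1 of 48 rose and 15 fell (2 and 15 adjusted over the list alone). Wnt genes had a median log2 change of -0.30 (camera adjusted p = 0.00361, adjusted p = 0.279 with an estimated correlation). The ligand gene Wnt6 was 4.67-fold (-2.22 ± 0.28, adjusted p = 0.00012) lower and the receptor gene Lgr6 3.17-fold (-1.67 ± 0.22, adjusted p = 0.000205) lower, while Fzd5, a receptor, was 3.05-fold (1.61 ± 0.22, adjusted p = 0.000239) higher. Among TGF-beta and BMP genes 2 of 38 rose and 10 fell (2 and 14 adjusted over the list alone), with Bmp1, a protease of matrix proteins, 2.43-fold (-1.28 ± 0.20, adjusted p = 0.000573) lower. TGF-beta and BMP genes had a median log2 change of -0.43 (camera adjusted p = 0.0164, adjusted p = 0.498 with an estimated correlation), and the call ended without PN9 replicate 3 (the highest adjusted p with 1 array left out, 0.0599). Among epithelial transcription factors 14 of 50 rose and 2 fell (15 and 3 adjusted over the list alone). Epithelial factors had a median log2 change of 0.32 (camera adjusted p = 0.0198, adjusted p = 0.592 with an estimated correlation), and this call ended without PN9 replicate 2 (the highest adjusted p with 1 array left out, 0.0897). Elf3, an ETS factor of epithelia, was 3.2-fold (1.68 ± 0.30, adjusted p = 0.00143) higher and Hopx, a homeodomain protein, 3.96-fold (1.99 ± 0.30, adjusted p = 0.000466) higher.

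Among wound and hyperproliferation genes from PN9 to PN20 7 of 14 rose (9 higher and 1 lower adjusted over the list alone). Wound genes had a median log2 change of 0.64 (camera adjusted p = 0.00833, adjusted p = 0.478 with an estimated correlation). Among glutathione and xenobiotic genes 11 of 45 rose (13 adjusted over the list alone), with Gsr 3.72-fold (1.89 ± 0.22, adjusted p = 8.14e-05) higher. Glutathione genes had a median log2 change of 0.36 (camera adjusted p = 0.0128, adjusted p = 0.509 with an estimated correlation), with a median of 0.24 without PN9 replicate 3, and the call ended without PN9 replicate 3 (the highest adjusted p with 1 array left out, 0.0599). Among inflammatory genes 13 of 36 rose and 2 fell (14 and 2 adjusted over the list alone). Inflammatory genes had a median log2 change of 0.47 (camera adjusted p = 0.00553, adjusted p = 0.591 with an estimated correlation). Class II genes from PN9 to PN20 (2 of 11 rose, 2 adjusted over the list alone) had a median of 0.44 (camera adjusted p = 0.0488, adjusted p = 0.526 with an estimated correlation), and that call ended without PN9 replicate 2, PN14 replicate 3, PN20 replicate 1 or Klf4CN replicates 1 or 2 (highest adjusted p with 1 array left out, 0.121) and with the actin ratio as a covariate (median 0.14, adjusted p = 0.259). Retinoid genes went both ways (3 of 22 rose and 3 fell, 4 and 3 adjusted over the list alone; median log2 change 0.04, camera adjusted p = 0.845), with Aldh1a3, an enzyme that makes retinoic acid, 4.14-fold (2.05 ± 0.38, adjusted p = 0.00162) higher and Crabp1, a retinoic acid binding protein, 3.73-fold (-1.90 ± 0.35, adjusted p = 0.00159) lower.

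Among basal epithelium genes from PN9 to PN14 3 of 14 fell (2 higher and 5 lower adjusted over the list alone). Basal genes had a median log2 change of -0.43 (camera adjusted p = 0.0275, adjusted p = 0.614 with an estimated correlation), and the call ended without PN9 replicate 1 or PN14 replicate 1 (highest adjusted p with 1 array left out, 0.131). Among cornification genes 3 of 39 rose and 3 fell (5 and 7 adjusted over the list alone). Cornification genes had a median log2 change of -0.40 (camera adjusted p = 0.0389, adjusted p = 0.614 with an estimated correlation), with a median of -0.14 without PN9 replicate 2, and this call ended with quantile normalization, values as deposited, the actin ratio, array weights, either stricter filter and the mean of a gene's probe sets, and without PN9 replicate 2, PN14 replicates 1 or 2 or Klf4CN replicate 3 (highest adjusted p with 1 array left out, 0.262). From PN9 to PN20 the cornification list (4 of 39 rose and 4 fell, 4 and 10 adjusted over the list alone; median log2 change -0.23, camera adjusted p = 0.422), the Notch list (3 of 28 rose and 3 fell, 3 and 3 adjusted over the list alone; median log2 change -0.09, camera adjusted p = 0.64) and the corneal list (2 of 12 rose and 2 fell, 2 and 2 adjusted over the list alone; median log2 change 0.17, camera adjusted p = 0.977) did not pass.

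Among other cell types, 2 of 11 hair follicle genes fell (3 adjusted over the list alone) from PN9 to PN14. Hair follicle genes had a median log2 change of -0.80 (camera adjusted p = 0.0113, adjusted p = 0.53 with an estimated correlation), with a median of -0.41 without PN9 replicate 1 and -0.50 without PN14 replicate 2, and the call ended without PN9 replicate 3 (the highest adjusted p with 1 array left out, 0.1). Among myeloid genes from PN14 to PN20 2 of 24 fell (6 adjusted over the list alone). Myeloid and mast cell genes had a median log2 change of -0.40 (camera adjusted p = 3.69e-05, adjusted p = 0.147 with an estimated correlation). The lymphocyte list had 0 of 16 genes called by limma from PN9 to PN20 (median log2 change -0.05, camera adjusted p = 0.725), with 0 higher and 1 lower at an unadjusted p under 0.05, and the melanocyte and Schwann cell list (1 of 12 rose and 2 fell, 4 and 2 adjusted over the list alone; median log2 change 0.56, camera adjusted p = 0.845) did not pass.

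The sex-linked list did not pass from PN9 to PN20 (median log2 change 0.47, camera adjusted p = 0.984). Xist stood between 11.88 and 13.09 on the log2 scale on 7 arrays and between 5.736 and 6.494 on the other 5. Eif2s3y, a gene of the Y chromosome, stood between 9.05 and 9.70 on those 5 arrays and between 4.034 and 4.318 on 6 of the 7, and at 5.905 on Klf4CN replicate 3.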
